A study of Solanum lycopersicum with 6 samples.

How the data were processed

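Bisulfite sequencing of embryo DNA was analysed for 6 libraries of the tomato cultivar Micro-Tom, 3 from wild-type plants and 3 from plants with a knockout of SlNRPD1, referred to as nrpd1. Embryos were taken 21 days after flowering in both genotypes. Groups were taken from the sample titles and genotype labels. The short design text of the series speaks of RNA sequencing, whereas the series type, the library labels and the processed tables are of DNA methylation, and only methylation was analysed here. Nothing in the labels says whether the 3 libraries of a genotype came from separate plants.

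Genomic DNA was converted with bisulfite before sequencing, per the labels' protocols. Bisulfite turns unmethylated cytosine into uracil, which is read as thymine, so that the share of reads still showing cytosine estimates methylation. Incomplete conversion would therefore raise apparent methylation, mostly in the CHH context, where true levels are low. Trim Galore 0.6.7 and Bismark 0.24.0 are listed in the submitters' processing notes. The caller of differentially methylated regions, its thresholds, the annotation tool, the conversion rate and the sequencing depth are not given in the sources used here. Sequence names in the tables give SL4.0 as the assembly, and coordinates are printed in that build.

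The 3 deposited tables list regions that the authors called as different between the genotypes, with 1 table each for cytosines in the CG, CHG and CHH contexts (H stands for A, C or T). The authors gave the methylation of each region as a fraction between 0 and 1, with 1 mean per genotype, per the file headers. These means are printed here as percentages, and differences, always nrpd1 minus wild type, as percentage points. The deposited difference column equalled the difference of the deposited means in every region. A further deposited column is the authors' region statistic, a score with no fixed range that is signed opposite to the difference. It is not a p-value, and it served here only to describe regions and to select the 50% of regions with the larger values. The tables also give the width of each region, its number of cytosines, an annotated feature, the assigned gene and the distance to its transcription start.

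No listed region had an absolute difference below 0.1, fewer than 4 cytosines or a width under 50 bp. Methylation outside the listed regions was not analysed here, so neither genome-wide levels nor the number of regions that could have been called are known. Because the values are means per genotype without read numbers, the spread between the 3 libraries could not be computed, and neither a test between samples nor an interval for a single region could be made. Regions had been called for their difference, with thresholds that are unknown here, so the sizes of change are those of a selected set.

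Regions with a negative difference were called lower and the others higher. Shares of regions were given Wilson 95% intervals, which cover counting error only and treat regions as independent. Consistency along the genome was tested by an exact two-sided sign-flip permutation over the 12 chromosomes, in which each chromosome contributed 1 value and all 4096 sign patterns were enumerated. The smallest p this test can give is 0.000488. Chromosomes are blocks of one genome measured in the same libraries and are not biological replicates, so these p-values say how evenly a pattern was spread over the genome and not how it would vary between plants. Features were compared between lower and higher regions with Fisher's exact test, two-sided, and with the sign-flip test. Fisher's test also treats regions as independent, so its p-values cover neither clustering of regions nor variation between plants. Benjamini-Hochberg adjustment was applied within the family of tests where a p is printed as adjusted, and all other p-values are unadjusted.

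Overlap between contexts was counted when regions shared at least 1 bp. It was compared with 100 random placements of regions of the same widths on the same chromosome, for which the smallest two-sided p is 0.0198. Chromosome lengths were taken from the furthest region end listed for each chromosome, since no genome sequence was used here. For position, chromosomes were divided into 1 Mb bins, and the bins were grouped into 3 classes of similar size by the number of genes named in the tables. Of 27473 genes named, 5.84 per Mb fell in the gene-poor bins and 84.2 per Mb in the gene-rich bins. A gene was named only where a listed region was assigned to it, so these classes are not independent of the regions counted in them, and a split by position alone, the outer 20% at either end of each chromosome against the middle 60%, is given beside them. Unplaced sequence, listed as chromosome 0, was left out of tests over chromosomes. The methylation that was left in nrpd1 was expressed as the percentage of the wild-type level, with the median taken over regions.

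The rule for named regions was fixed before the data were examined. In each context it took, among regions in the promoter or body of a gene with at least 10 cytosines, the 6 genes with the greatest loss and the 4 with the greatest gain. It added the 10 genes with a lower region in all 3 contexts and the greatest summed loss. The tables give gene identifiers without names, and the reference table of gene symbols used here held 0 of these identifiers. Identifiers are therefore printed for 2 genes that gained and 2 that lost methylation, and other regions are named by position and annotated feature. For the same reason none of the 12 gene lists fixed beforehand, which covered DNA methylation and demethylation factors, embryo and meristem regulators, seed maturation and storage, auxin, abscisic acid and gibberellin, cell cycle, fruit ripening, endosperm and seed coat, transposon proteins, defence receptors and housekeeping genes, was tested, and the SlNRPD1 gene itself was not identified.

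Alternatives covered a stricter difference (at least 0.5 in CG, 0.4 in CHG and 0.2 in CHH), a minimum of 10 cytosines, merging of regions within 200 bp, base pairs in place of regions, other overlap criteria, random placement within the same 1 Mb bin, promoters set by distance, bins of 2 Mb and the outer 20% at either end of chromosomes in place of gene density. The code was tested on simulated regions. A planted overlap of 40.63% was measured as 40.5%, and a planted density ratio of 3 as 2.98. Without an effect, 12 of 200 sign-flip tests and 3 of 100 placement tests fell below 0.05. For these tests regions were spread evenly at random along chromosomes and chromosome values were drawn independently. The listed regions were clustered, so these rates may not hold for them. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.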

Results

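DNA methylation was compared between wild-type and nrpd1 embryos of the dwarf tomato cultivar Micro-Tom at 21 days after flowering, with 3 bisulfite libraries per genotype. NRPD1 is the largest subunit of RNA polymerase IV, a plant enzyme that makes the precursors of the small RNAs which guide new methylation to DNA (RNA-directed DNA methylation). Plant DNA is methylated in 3 contexts. CG and CHG sites are symmetric between the strands and can be maintained after replication by dedicated methyltransferases, whereas methylation at asymmetric CHH sites has to be re-established. The title of the series names embryo development and methylation outside the CG context as its subject, so the comparison asks which contexts and which parts of the genome differed in nrpd1 embryos. The authors listed 132092 differentially methylated regions, of which 13010 were in the CG, 42277 in the CHG and 76805 in the CHH context. Each region carried the authors' mean level in each genotype. Read depth is unknown, and there were no values for single libraries, so no error between libraries can be attached to any level below.

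Most regions were less methylated in nrpd1 embryos, and the excess of losses was greatest in the CHH context. Of the CHH regions, 73614 were lower and 3191 were higher, so that 95.8% were losses (Wilson 95% interval 95.7 to 96.0). In CHG, 37203 regions were lower and 5074 higher, a share of losses of 88.0% (87.7 to 88.3). In CG, 8805 were lower and 4205 higher, or 67.7% losses (66.9 to 68.5). CHH losses covered 61.1 Mb of sequence, against 14.3 Mb for CHG losses and 2.24 Mb for CG losses, while gains covered between 1.01 and 1.96 Mb in the 3 contexts.

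**Figure D1:**
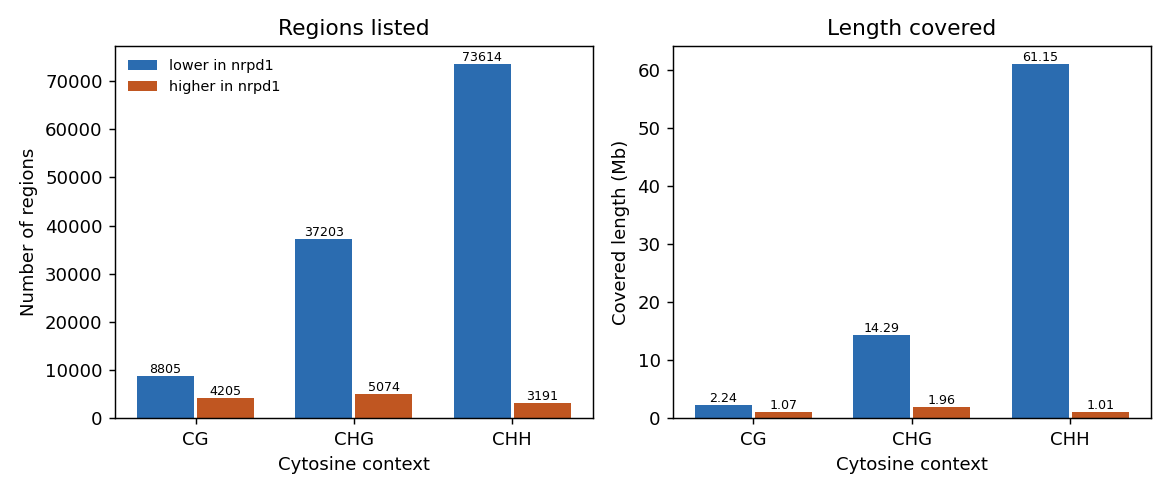
Number of listed regions (left) and covered length in Mb (right) per cytosine context, with regions lower in nrpd1 in blue and regions higher in nrpd1 in orange. Losses outnumbered gains in each context, by 73614 to 3191 regions in CHH and by 8805 to 4205 in CG.

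The excess of losses was present on each of the 12 chromosomes in all 3 contexts (exact sign-flip permutation, adjusted p = 0.000488, the smallest this test can give). The share of losses ranged from 94.3% on chromosome 12 to 97.0% on chromosome 2 in CHH, from 80.5% on chromosome 7 to 93.9% on chromosome 6 in CHG, and from 59.6% on chromosome 4 to 79.3% on chromosome 6 in CG. It was higher in CHH than in CHG by 7.86 points ± 4.17 (SD over 12 chromosomes) and higher in CHG than in CG by 20.2 points ± 4.34, each on 12 of 12 chromosomes (exact sign-flip permutation, p = 0.000488). Fisher's exact test over regions gave odds ratios of 3.15 and 3.502 for the same contrasts.

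Listed losses started from low levels in CHH and from high levels in CHG and CG. In CHH losses the median level was 25.1% in wild type and 8.00% in nrpd1, and the median region held 32.0% of its wild-type level. The corresponding medians in CHG losses were 67.9% and 34.7%, with 52.6% of the wild-type level left, and in CG losses 74.7% and 44.1%, with 60.8% left. In points, the median region fell by 15.7 in CHH (SD of the chromosome medians 0.571), fell by 27.9 in CHG (SD 0.449) and fell by 25.9 in CG (SD 0.462). No listed region differed by less than 10 points, which by itself caps the share left at a lower value where the wild-type level is low, so the shares left are not comparable between contexts.

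Gains were similar in size to losses in CG but small in CHH. CG regions that were higher in nrpd1 went from a median of 38.5% to 69.9%, with a median change of 26.4 points, and CHG gains from 33.4% to 63.3%, with 24.0 points. CHH gains went from 13.9% to 25.02%, with a median change of 10.8 points. Of the CHH gains, 78.3% were below 12 points, close to the smallest difference in the tables, and 28 regions reached 20 points, compared with 18790 CHH losses. CHH losses were also wider, with a median width of 635 bp against 206 bp for gains. The listed regions had been called by the authors as different, with thresholds not given in the sources used here, so these medians describe the called regions and not the genome. The number of regions depended on the size of difference required, and with a minimum of 50 points in CG 171 losses and 124 gains were left.

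**Figure D2:**
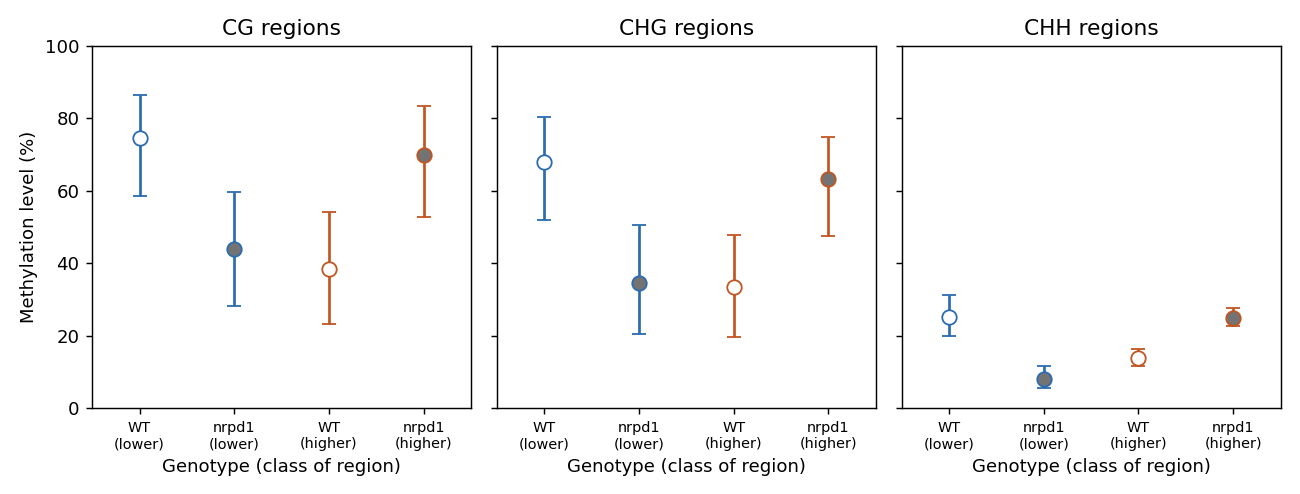
Median methylation level in percent of wild-type (open symbols) and nrpd1 embryos (filled symbols) in regions lower (blue) and higher (orange) in nrpd1, for CG, CHG and CHH; bars span the quartiles over regions and are not errors between libraries. CHH losses went from a median of 25.1% to 8.00%, and CG losses from 74.7% to 44.1%.

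Losses lay near genes more often than gains did. Promoters, annotated within 2 kb of the transcription start, held 32.7% of CHH losses but 3.32% of CHH gains, a difference of 29.4 points ± 2.60 (SD over chromosomes). In CHG, 31.6% of losses and 7.31% of gains lay in promoters (24.3 points ± 2.46), and in CG 31.6% and 16.1% (14.7 points ± 5.06). Distal intergenic sequence held 92.4% of CHH gains and 57.4% of CHH losses, 78.4% and 55.1% in CHG, and 64.7% and 51.2% in CG. Exons held 11.4% of CG gains and 6.81% of CG losses, while introns held 4.38% and 8.02%.

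For promoters, the difference had the same sign on 12 of 12 chromosomes in each context (exact sign-flip permutation, adjusted p = 0.000488), and Fisher's exact test gave odds ratios of 14.2 in CHH, 5.87 in CHG and 2.39 in CG (adjusted p = 5.75e-82 in CG). The Fisher p counts clustered regions from the same libraries as independent and overstates the evidence. For exons, CG gains had the larger share on 12 of 12 chromosomes (exact sign-flip permutation, adjusted p = 0.000977), whereas in CHG the exon shares of 3.93% for losses and 4.45% for gains were not distinguished by either test (sign-flip adjusted p = 0.470). Features were those of the authors' annotation. Losses and gains were not matched for width or for position along the chromosome, and gene-rich parts held most losses. The difference in feature was therefore not separated from that in position, and the share of each feature in the genome is not known here.

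Within the losses, promoters lost more CHH and CHG methylation than distal intergenic regions. In promoters within 1 kb of the transcription start, CHH methylation went from a median of 26.1% to 7.58%, leaving 29.5% of the wild-type level, and in distal intergenic regions from 25.2% to 8.61%, leaving 34.4%. CHG methylation went from 67.1% to 31.9% in these promoters, leaving 49.1%, and from 70.7% to 38.2% in distal regions, leaving 55.3%. Each of these differences in the share left had the same direction on 12 of 12 chromosomes (exact sign-flip permutation, adjusted p = 0.000732). Promoters and distal regions were not matched for position along the chromosome. Gene bodies started from lower levels, 21.4% in CHH and 53.2% in CHG, and lost fewer points than distal regions. The median region fell by 14.5 points in gene bodies and fell by 15.03 in distal regions in CHH, and fell by 25.5 and 27.7 points in CHG, with the smaller loss in points in gene bodies on 12 of 12 chromosomes (exact sign-flip permutation, adjusted p = 0.000586). As a share of the wild-type level, gene bodies were left with less than distal regions, 28.5% against 34.4% in CHH and 45.9% against 55.3% in CHG. This held on 12 of 12 chromosomes in each (exact sign-flip permutation, adjusted p = 0.000732). The gene-body shares were not matched on the wild-type level. In CG, the median region fell by 25.2 points in promoters and fell by 26.4 in distal regions. For promoters this was the reverse of the direction in CHH and CHG. Promoters had the larger CG loss on 3 of 12 chromosomes (exact sign-flip permutation, adjusted p = 0.00732). In gene bodies CG fell by 24.9 points, a smaller loss than in distal regions on 12 of 12 chromosomes (exact sign-flip permutation, adjusted p = 0.000586). These CG points were not matched on the wild-type level. The CG share left was 60.8% in promoters and 60.7% in distal regions and was not distinguished (exact sign-flip permutation, adjusted p = 0.969). Matching on the wild-type level changed this to 1.77 points more left in promoters, on 11 of 12 chromosomes (exact sign-flip permutation, p = 0.000977), and reduced the CHG difference between promoters and distal regions from -6.40 to -3.37 points, on 12 of 12.

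Losses were concentrated towards the gene-rich ends of the chromosomes, whereas CHG and CHH gains were sparsest there. The gene-rich bins, in which genes were densest, held 209.6 CHH losses per Mb and the gene-poor bins 17.7 per Mb, a ratio of 11.9. CHG losses reached 115 and 8.23 per Mb (ratio 14.0) and CG losses 28.1 and 1.93 per Mb (ratio 14.6). CHH gains were sparser in the gene-rich bins, with 2.27 against 4.54 per Mb in the gene-poor bins (ratio 0.501), as were CHG gains, with 3.88 against 6.97 per Mb (ratio 0.557). Both were densest in bins of middle gene density, with 5.08 CHH gains and 8.59 CHG gains per Mb. CG gains were denser in the gene-rich bins, with 7.45 against 3.23 per Mb, a ratio of 2.31 that was far below that of CG losses.

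**Figure D3:**
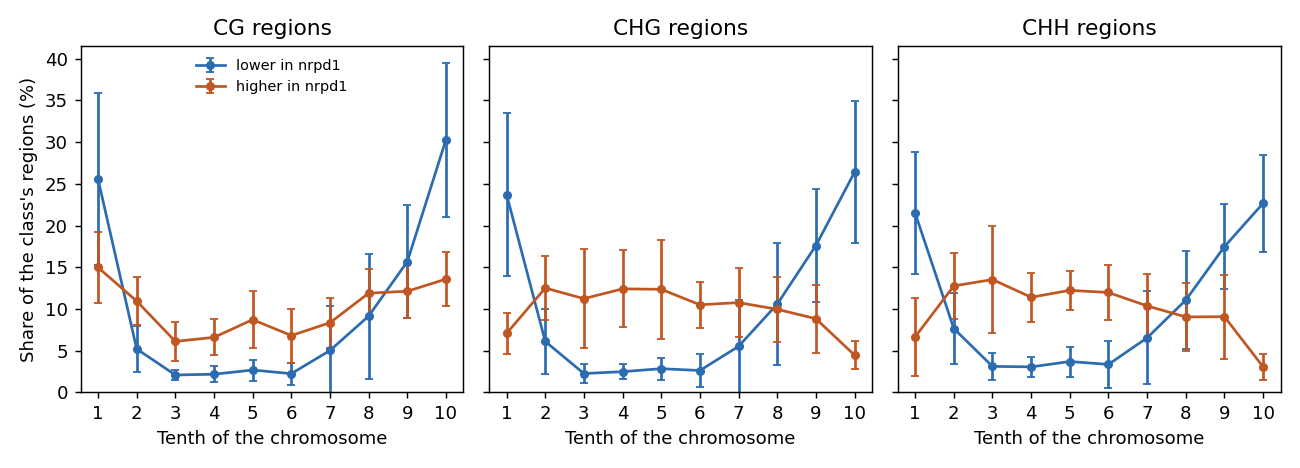
Share of the regions of a class in percent that fell in each of 10 equal parts of a chromosome, from one end to the other, for CG, CHG and CHH; points are means and bars SDs over the 12 chromosomes, with regions lower in nrpd1 in blue and higher in orange. On average the first part held 21.5% of CHH losses and 6.65% of CHH gains, and the last part 22.7% and 3.05%.

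Each difference between gene-rich and gene-poor bins had the same sign on 12 of 12 chromosomes (exact sign-flip permutation, adjusted p = 0.000488). Bins were classed by genes named in the tables, a gene being named only where a region was assigned to it, so the classes depend in part on the regions counted and the ratios for losses are inflated to an unknown extent. By position alone, with the outer 20% at either end of each chromosome set against the middle, the ratios were 3.31 for CHH losses, 4.06 for CHG losses, 4.94 for CG losses, 1.61 for CG gains, 0.678 for CHH gains and 0.736 for CHG gains, in the same direction on 11 of 12 chromosomes for each. How much of each class of bins could be assayed is not known, so densities also depend on how well reads could be placed in repetitive interior sequence.

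The balance of gains and losses changed along the chromosomes. By position alone, 8.46% of CHH regions, 25.2% of CHG regions and 49.7% of CG regions were gains in the middle 60% of chromosomes, against 1.86%, 5.75% and 24.3% in the outer 20% at either end. The difference was 7.85 points ± 4.33 in CHH and 22.8 points ± 14.1 in CHG, positive on 11 of 12 chromosomes (exact sign-flip permutation, p = 0.000977), and 27.9 points ± 13.4 in CG, positive on 12 of 12 (p = 0.000488 in the same exact test). These shares follow the losses more than the gains, since CHH losses went from 163.8 to 49.5 per Mb between the outer and middle parts and CHH gains from 3.10 to 4.57 per Mb, while CG gains were themselves sparser in the middle, with 4.36 against 7.01 per Mb. The contrast was larger between classes of bins, which depend in part on where losses were listed. In the gene-rich bins, 1.07% of CHH regions, 3.27% of CHG regions and 21.0% of CG regions were gains. In the gene-poor bins, which hold few losses partly by construction, these shares were 20.4%, 45.9% and 62.6%. The difference between the classes of bins was 20.5 points ± 6.72 in CHH, 42.9 points ± 14.6 in CHG and 41.3 points ± 12.6 in CG (SD over chromosomes), positive on 12 of 12 chromosomes in each (exact sign-flip permutation, p = 0.000488). In the gene-poor bins CG gains outnumbered CG losses, 807 to 482, on 9 of 12 chromosomes (exact sign-flip permutation, adjusted p = 0.0144). That majority was not seen when the middle 60% of each chromosome was taken in place of gene-poor bins, with its 49.7% (exact sign-flip permutation, p = 0.550).

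Methylation was also retained to different degrees. CHH losses in the gene-poor bins were left with 38.8% of the wild-type level and those in the gene-rich bins with 30.3%, from wild-type medians of 24.3% and 25.1%. CHG losses were left with 62.1% and 50.99%. Both differences were positive on 12 of 12 chromosomes (exact sign-flip permutation, adjusted p = 0.000732). The CHG difference, 11.4 points as a mean over chromosomes, was 6.60 points after matching on the wild-type level. By position alone, CHH losses were left with 35.8% in the middle 60% of chromosomes and 30.6% in the outer parts, and CHG losses with 56.2% and 51.3%, on 12 of 12 chromosomes each. CG losses were left with 58.9% in the gene-poor and 61.1% in the gene-rich bins, which was not distinguished (exact sign-flip permutation, adjusted p = 0.0928). Matched on the wild-type level, the CG difference was -4.02 points (p = 0.0156 in an exact sign-flip permutation over 10 chromosomes).

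CHG losses mostly fell on CHH losses, while most CHH losses overlapped no listed CG or CHG loss. Of the CHG losses, 75.7% overlapped a CHH loss, against 11.4% on average for random placement on the same chromosome. Of the CG losses, 45.9% overlapped a CHH loss (random 10.3%) and 39.3% a CHG loss (random 3.13%). In the other direction, 35.4% of CHH losses overlapped a CHG loss, 46424 (63.1%) overlapped neither a CG nor a CHG loss, and 2829 (3.85%) overlapped both. Smaller CG or CHG changes at these CHH losses may have gone unlisted. Of the listed losses, 86.3% in CHG and 82.7% in CG reached 20 points, against 25.5% in CHH. Gains coincided as well, with 20.8% of CG gains (random 0.421%) and 12.9% of CHH gains (random 0.455%) overlapping a CHG gain.

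Each of these overlaps with its random value exceeded all 100 placements (permutation test, adjusted p = 0.0216, with 0.0198 the smallest p possible before adjustment). Placement within the same 1 Mb bin, which keeps the regional density, raised the random values to 22.6% for CHG losses and 21.0% for CG losses in CHH losses and to 7.09% for CG losses in CHG losses, and the observed overlaps stayed above all placements. Both kinds of placement may have covered sequence where no region could be called, so the random values may be too low. Gains and losses rarely met. CHG gains overlapped CHH losses in 2.30% of cases (random 10.99%), and 0 of 3077 CHH gains on the 12 chromosomes overlapped a CG or a CHG loss. CG gains overlapped CHH losses in 9.81% of cases, which was not distinguished from random placement on the same chromosome (10.1%, permutation p = 0.673). Against placement in the same bin this was a deficit (12.95%, permutation p = 0.0198), and when regions within 200 bp were counted it became an excess of 1.53 times.

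**Figure D4:**
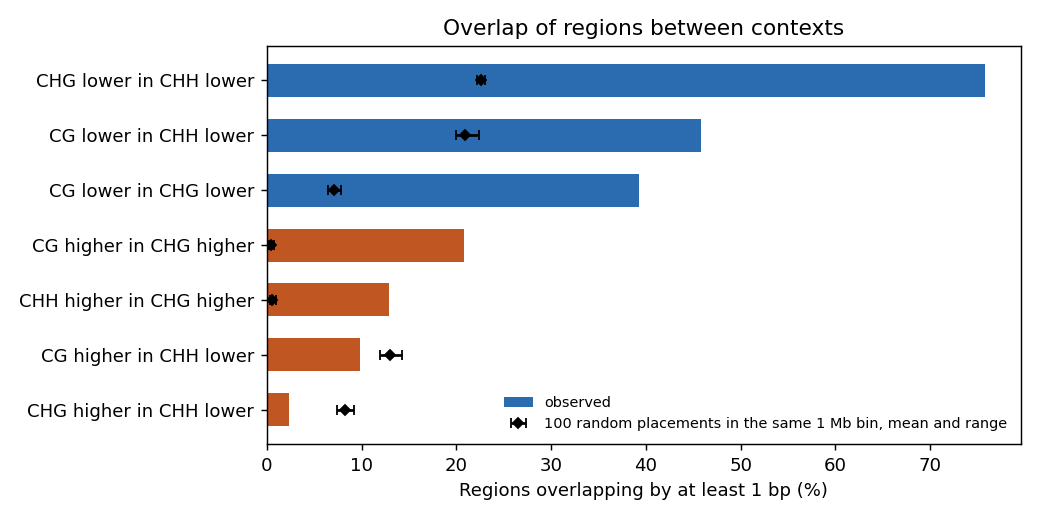
Percentage of regions of the first class that overlapped a region of the second by at least 1 bp (bars, blue for losses and orange for gains), with the mean and range of 100 random placements in the same 1 Mb bin (diamonds with bars). CHG losses overlapped CHH losses in 75.7% of cases against 22.6% in random placement.

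CG losses that coincided with CHH losses differed from those that did not. The 4036 CG losses overlapping a CHH loss went from a median of 80.2% to 51.5%, and 2.58% of them lay in exons. The 4765 others went from 69.3% to 37.4%, and 10.4% of them lay in exons. The wild-type level was higher in the overlapping group by 11.03 points ± 2.04, and the exon share was higher in the other group by 7.66 points ± 1.94 (SD over chromosomes), each on 12 of 12 chromosomes (exact sign-flip permutation, adjusted p = 0.000651).

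Most genes named in the tables had a CHH loss in their promoter or body. Of the 27473 genes, 20098 (73.2%) had such a CHH loss, 12017 (43.7%) a CHG loss and 3684 (13.4%) a CG loss, and 2267 (8.25%) had losses in all 3 contexts. Gains in the promoter or body were listed for 1324 genes in CG, 863 in CHG and 203 in CHH, and 20 genes had gains in all 3. These counts follow the assignment of each region to 1 gene by the authors, and genes without any listed region are not among the 27473.

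Of the 10 genes with the greatest summed loss over the 3 contexts, 9 had their losses in the promoter in each context. Among all 2267 genes with losses in the 3 contexts, 1450 had a promoter loss in each, so promoters were the usual place in this group. The greatest was at Solyc06g060720.3 on chromosome 6, where a CHH region spanning the transcription start (36408612 to 36410612, SL4.0) went from 41.3% in wild type to 7.14% in nrpd1. A CHG region within it (36408736 to 36410427, 44 cytosines) went from 89.4% to 16.3%, and a CG region (36408999 to 36410429, 49 cytosines) from 95.7% to 54.1%. Next was Solyc12g013960.3 on chromosome 12, with promoter regions that went from 38.8% to 9.56% in CHH (4831789 to 4833662), from 88.5% to 17.1% in CHG (4831957 to 4833084) and from 89.1% to 50.1% in CG (4831937 to 4833156). In the exception, on chromosome 11, the CHG region (3805209 to 3806036) was annotated as exon, 568 bp inside the gene from its transcription start, and went from 83.3% to 19.9%.

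Single regions reached larger changes, ranked here among regions in promoters or gene bodies with at least 10 cytosines. In this set the greatest CHG loss lay across a transcription start on chromosome 4 (57069384 to 57070089) and went from 87.1% to 8.90%. The greatest CG loss of this set lay 83 bp inside a gene on chromosome 8 (59833001 to 59833326), annotated as promoter, and went from 77.1% to 5.85%. The greatest CHH loss of this set, 1165 bp upstream of a gene on chromosome 4 (62907032 to 62907232), went from 73.9% to 13.6% over 14 CHH cytosines. The next, 715 bp upstream of another gene on the same chromosome (58673077 to 58673495), went from 69.0% to 10.3% over 61 cytosines. All 6 of the CHG and all 6 of the CHH losses named by the rule were annotated as promoter, as were 5 of the 6 CG losses. The other lay in a 3' UTR on chromosome 10 (239706 to 240270, 81.9% to 21.0%). The rule admitted only promoters and gene bodies, where promoters prevail. Before the minimum of 10 cytosines, promoters held 24092 CHH, 11769 CHG and 2779 CG losses. Exons held 2512, 1461 and 600, and introns 2638, 2584 and 706. The named losses therefore show no preference of the strongest losses for promoters.

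Gains of similar size were found in CG and CHG in the same set of promoter and gene-body regions. The greatest CG gain of this set lay in exon 3 of 3 of Solyc02g014773.1 on chromosome 2 (17228672 to 17228966), where 10 CG cytosines went from 14.5% in wild type to 94.4% in nrpd1. The greatest CHG gain of this set was annotated as exon at the 3' end of Solyc10g061870.1 on chromosome 10 (21590047 to 21591466), 2351 bp from its transcription start, and went from 22.0% to 85.6% over 68 cytosines. One gene on chromosome 1 had both a CHG gain (3718106 to 3719195, 28.0% to 87.3%) and a CHH gain (3718177 to 3719217, 5.66% to 26.2%) in its 5' UTR. The greatest CHH gain of this set, across a transcription start on chromosome 9 (326793 to 326996), went from 7.31% to 31.7%. These are extremes of mean values with unknown depth, several of them over few cytosines, and their spread between libraries could not be checked.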

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

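The selection of regions by the authors' statistic, the tests of gain shares by position, of the CG majority in gene-poor bins and of the methylation left were chosen after the main results were seen, and the other alternatives before the data were examined. The share of losses stayed above 50% on the same side of the threshold in all 18 alternatives (57.97% to 99.9%), the 9 alternatives for promoters kept sign and call, and no alternative turned a density ratio. Numbers of regions followed the minimum difference. Requiring 0.5, 0.4 and 0.2 left 171 CG, 4166 CHG and 18790 CHH losses and 124, 416 and 28 gains. At least 10 cytosines left 4948 CG and 21252 CHG losses and 2559 and 3380 gains. The 50% of regions with the larger statistic held 4238 CG, 18296 CHG and 38099 CHH losses and 2267, 2843 and 304 gains. Median changes moved by construction with the stricter difference, and they also moved with the larger statistic. The minimum of 10 cytosines does not select on the difference, and with it only the CHG medians moved beyond the SD of the chromosome medians. With the stricter difference CG fell by 54.7, CHG fell by 44.6 and CHH fell by 23.5 points in losses, and gains were 54.7, 45.8 and 22.6 points. With at least 10 cytosines CHG fell by 28.5 points in losses and gained 25.4. In the 50% with the larger statistic CG fell by 27.0, CHG fell by 29.99 and CHH fell by 19.3 points in losses, and gains were 27.4, 26.7 and 11.1 points. The overlap of CG gains with CHH losses, 0.976 times random (permutation p = 0.673), was 0.757 times with placement in the same bin and 0.580 times with 50% of the region covered, and reversed to 1.53 times within 200 bp (permutation p = 0.0198 each). The share of CG gains in gene-poor bins, 62.6%, was 49.7% in the middle 60% of chromosomes, not distinguished from 50% (exact sign-flip p = 0.550, 7 of 12 chromosomes with more gains), and was 73.3% with the stricter difference, where it missed the threshold (exact sign-flip p = 0.0571) with 10 of 12 chromosomes in its direction. The difference in the share of gains among listed regions, gene-poor over gene-rich, shrank with the split by position, from 20.5 to 7.85 points in CHH, from 42.9 to 22.8 in CHG and from 41.3 to 27.9 in CG. Of 12 alternatives for the methylation left, 9 kept the call, and 3 in CG turned an undistinguished difference into a distinguished one, -4.02 and 1.77 points with matching and -2.27 points with matching and position. The cause was not tested for these overlaps and shares. No paired analysis was possible because the tables give 1 mean per genotype and no value per replicate. For the same reason leaving out replicates was not run, a stricter p was not run as no p is given, and gene list tests were not run for want of names. Unknown depth leaves the error of each level unknown.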

Other observations

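The tests on conversion, on gains by position, on CHH gains near the smallest listed difference and on CG losses against CG gains were chosen after the results were seen, as were the regions, bins and sequences picked out here by size. Those on flanking CHH losses, on matched wild-type levels and on the methylation left by position were also added after the main results, but what each would show was written down before its own value was seen.

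Unplaced sequence had a larger share of gains than the 12 chromosomes taken whole. Of 167 CHH regions listed there, 114 were higher in nrpd1 (68.3%, Wilson 95% interval 60.9 to 74.8), compared with 4.01% of CHH regions on the 12 chromosomes. In CHG 41 of 64 regions were higher (64.1%, 51.8 to 74.7) against 11.9%, and in CG 15 of 19 (78.9%, 56.7 to 91.5) against 32.3%. The contrast was smaller against the gene-poor bins, where gains were 20.4% of CHH, 45.9% of CHG and 62.6% of CG regions. In these bins single chromosomes reached 37.1% in CHH, 67.6% in CHG and 74.4% in CG, so only the CHH share lay above all of them by a wide margin. On the chromosomes, CHH gains were densest between 10 and 11 Mb of chromosome 6, where 42 gains and 6 losses were listed and the gains went from a median of 12.9% to 24.0%.

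Some regions were long. There were 98 CHH losses wider than 5 kb, the widest spanning 15761 bp. By the statistic in the authors' deposited table, the leading CHH loss covered 9153 bp from a promoter on chromosome 3 (47219222 to 47228374, SL4.0) and went from 39.4% to 9.57%. In the same deposited table from the authors, a leading CHG gain covered 6580 bp on chromosome 7 (26384865 to 26391444), annotated as exon, and went from 5.67% to 39.6%. Gains in CG, CHG and CHH coincided at 143 CHH gains (4.65%).

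CHH and CHG gains, unlike CG gains, were denser in gene-poor than in gene-rich bins, which could also come from the way bins were classed, a failure of bisulfite conversion or chance calls, but by position alone CHH gains were denser in the middle of chromosomes by 1.46 per Mb (SD 1.01, 11 of 12 chromosomes), so the classing is argued against as the whole cause. Uniform failure in the nrpd1 libraries would have to reach 12.6% to give the median CHH gain, 41.4% for CHG and 49.0% for CG. It would set a floor under every CHH level. Yet nrpd1 CHH levels in CHH losses had a median of 8.00%, an upper quartile of 11.6% and a median of 9.32% in gene-poor bins. These levels argue against uniform failure alone as the source of gains of median size. Since no gain under 10 points was listed, the comparison cannot exclude a smaller failure that added to noise in the CHH gains. Of the CHH gains, 398 (12.9%) overlapped a CHG gain, against at most 1.01% in placements in the same bin. For these, independent chance calls falling anywhere in a bin are argued against. Placements may also have covered sequence where no region could be called, so chance calls confined to the same assayable sequence were not excluded. For the other 2679, 78.8% lay within 2 points of the smallest listed difference, 10 points, and 4.44% exceeded 15 points, so that chance calls and a small real rise cannot be told apart, and conversion or alignment that differed locally, or inherited differences between the plant lines, were not tested.

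CG losses without a CHH or CHG loss, 3748 regions or 42.6% of CG losses, may be ordinary CG variation between plant lines or may flank sites of RNA polymerase IV action. As variation that runs both ways alike they should lie where CG gains lie. The share in the first and last of 10 equal parts of the chromosomes was 26.5 points higher than for all CG gains (SD 12.9, 12 of 12 chromosomes), although exon shares were 11.5% in both. The gains were not restricted in the same way, and 20.8% of them overlapped a CHG gain. CHG gains lay in these end parts in 11.5% of cases. How much of the gap came from these unlike sets was not tested, so it does not decide the question. Within 1 kb of a CHH loss lay 55.0% of the CG losses without a CHH or CHG loss, against 27.0% in random placements in the same bin that overlapped none. CG gains were also near CHH losses more often than random, 39.8% against 16.9%, so flanking and a shared preference for the same sequence cannot be told apart. The genotype difference itself stays open as an explanation of both.

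CHH losses kept more of their methylation in gene-poor bins and less in promoters, which could reflect different wild-type levels or the classing of bins. After matching on wild-type level in classes of 5 points, the share left was still 8.64 points higher in gene-poor than in gene-rich bins (SD 1.08, 12 of 12 chromosomes), and -5.61 points in promoters relative to distal regions (SD 0.601, negative on 12 of 12), and by position alone it was 6.18 points higher in the middle than in the outer parts (SD 1.66, 12 of 12), so neither is the whole cause. In CHG, matching reduced the differences to 6.60 and -3.37 points, so that part of them went with the wild-type level, and 3.15 points were left by position. One hypothesis is that a second pathway acting outside RNA-directed methylation maintains part of the CHH and CHG methylation in gene-poor sequence. No mutant of such a pathway was analysed here, and repeat content and depth of the bins remain untested. Promoters and distal regions were not compared at like chromosome positions, so their difference was not separated from that between parts of the chromosomes.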
